A study of Mus musculus with 6 samples.

How the data were processed

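RNA was analysed from 3 SRM deletion mutant and 3 wild type mouse kidneys. Per the labels' protocols, polyadenylated RNA was purified from 4 to 5 µg of total RNA and made into Ion Torrent total RNA libraries, and the labels give the stage as day 17 in one place and 17.5 in another. Groups and library numbers (328, 336 and 342; 330, 331 and 337) came from the labels. The groups share no number, so no pairing was fitted. The labels speak of 3 kidneys per genotype without saying whether these came from separate embryos or litters, so p-values measure the spread between these kidneys.

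The deposited signal values are whole numbers per gene that the authors had scaled to nearly equal totals. Per the submitters' processing notes the genome build was mm10 and bedtools was used. The aligner, annotation, filter, scaling method and whether reads or covered bases were counted are not given in the sources used here. In each library the signal values are rounded multiples of a fixed step, 0.863, 1.79, 0.793, 0.836, 2.23 and 3.42 in mutants 328, 336, 342 and wild types 330, 331, 337, with every value below 60000, the range used to find the step, within 0.55 of a multiple. Over all values that share was 99.7% and 99.6% in wild types 331 and 337 and 100% in the others. That tolerance tests nothing for the 3 steps below 1, where chance also gives 100%, and chance gives 61.4%, 49.3% and 32.2% for mutant 336 and wild types 331 and 337. Those 3 steps rest on a periodicity of the values of 0.119, 0.139 and 0.100 in mutants 328 and 342 and wild type 330, against at most 0.0374 after random jitter, and the rival step just above 1 would leave 14.2%, 24.8% and 18.5% of their values unmatched by exact rounding to a multiple. By that stricter count the steps chosen for wild types 331 and 337 left 1.25% and 0.868% unmatched, and a smaller rival step above 1 left 0% in each. The rival's finer grid holds the coarser one, so this count cannot decide against it, but it would give a periodicity of 0.569 and 0.357, where 0.689 and 0.862 were observed and the chosen steps give 0.701 and 0.865. The 2 depth classes are the same with either step. Their exact size is less certain than that of the steps above 1, where the periodicity was 0.562 to 0.862. Dividing totals by the step gave an estimate of each library's relative depth, and libraries with a step below 1 and above 1 were taken as 2 depth classes. As the unit of a step is unknown, no read counts were recovered and no interval for counting error is given. The lowest mean signal over the 6 libraries was 3146, so low genes appear to have been left out of the table.

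The authors also deposited a ratio of group means, the log2 of the means and of their ratio, and a p-value per gene. The deposited p-value equals a two-sided equal-variance test on unlogged values within 1% for 100% of genes. The authors' deposited table has 1009 genes with a p under 0.05, 660 higher and 349 lower in mutants. With no change and no structure shared by genes, 578.9 would be expected. After Benjamini-Hochberg adjustment of those p-values 0 pass, the lowest being 0.240.

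Genes were tested with limma 3.58.1 in R 4.3.3 (moderated variance with a trend on mean level) on log2(signal + 1), with Benjamini-Hochberg adjustment over 11578 genes and a threshold of 0.05. The filter, a value of at least 1 in at least 3 libraries, removed no gene. The design had foreseen counts or length-normalized values, and the branch for normalized values was used because the table holds scaled signal. Fold changes are on the log2(signal + 1) scale. In all, 23 gene lists covering 285 genes, 235 of them in the table, were fixed before the data were examined, together with the groups, the test, the naming rule and the settings to be varied. The 21 lists with at least 3 listed genes were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over lists. Of these, 2 passed with the preset correlation, 0 with an estimated correlation and 2 by fry. The form with an estimated correlation was the stricter one here even at a like correlation. For the endothelium list, estimated at 0.0105 against the preset 0.01, the unadjusted camera p was 0.128 against 0.0552. A call lost with that form therefore need not be lost to correlation between genes.

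The text names up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold whose 3 mutant values lie on 1 side of the 3 wild type values, with a mean of at least 5 and leaving out predicted models. It also names the Sall genes and, of each list, up to 4 members past the threshold or else the most abundant one. One gene that the rule selects is not reported here. Other list members past the threshold over the list alone are named as part of their list's count. Coordinates, transcript length and GC content come from GENCODE release M21 on GRCm38, the assembly also called mm10, for 11517 of 11578 genes, 10951 matched by symbol and 566 by synonym.

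The procedure was tested on simulated data for this comparison, 10 sets of 11578 genes with 200 changed. It recovered 65.8% of genes changed 2-fold, 96.0% at 3-fold, 97.6% at 4-fold and 100% at 8-fold, and 6.26% of calls were false. A list shifted by 0.5 on the log2 scale was called in 10 of 10 sets and 0 of 200 other list tests were. The simulated noise was independent between genes and alike in both groups. In the data the estimated correlation within the proximal tubule list was 0.461. The median within-group SD was 0.18 in mutants and 0.294 in wild types. The simulated error rates therefore need not hold for the gene and list calls here.

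The settings varied as fixed in advance were other pseudocounts, filters, quantile and median scaling, no trend, other thresholds, removal of erythroid genes, leaving out each library, and other set tests. Alternatives for counts were not run, since the table holds none. Added after the values were seen were the depth class as a covariate, each depth class alone, removal of a spline of length and GC content from each library, both together, camera with an estimated correlation in these 3 fits, limma's array weights, a pseudocount of 1000, a minimum mean of 10000 and the authors' test. Files were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.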

Results

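Polyadenylated RNA was sequenced from mouse kidneys taken near day 17 of embryonic development, 3 with a deletion of the SRM, the repression motif through which the zinc finger protein Sall1 binds the NuRD chromatin remodelling complex, and 3 wild type kidneys of the same stage. The deposited table gave 1 signal value per gene and library for 11578 genes. Totals lay between 555147910 and 559251769 in every library, because the authors had scaled the values. The spacing of the values differed between libraries and was used to estimate their relative depth. Against wild type 337, the shallowest, mutant 336 had an estimated 1.92 times and wild type 331 an estimated 1.54 times the depth. In mutants 328 and 342 and wild type 330 the spacing was estimated below 1, which rests on a weaker periodicity of the values and puts their depth at no less than about 3.44 times that of wild type 337. Mutant 336 and wild types 331 and 337 thus formed a class of lower depth and the other 3 libraries one of higher depth.

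The comparison asks which transcripts depend on the Sall1-NuRD interaction in the developing kidney, where the series title names nephron progenitors and the loop of Henle. Sall1 itself (chromosome 8, 89027235 to 89044162, mm10) had a mean signal of 146014 ± 15649 (SD, n = 3) in mutants and 166799 ± 12472 (SD, n = 3) in wild types, a log2 difference of -0.19 (SE 0.16, limma adjusted p = 0.481). The values were 146230, 161553 and 130258 in mutants 328, 336 and 342, and 176175, 152644 and 171578 in wild types 330, 331 and 337. A value per gene cannot show whether the deleted motif is present, so Sall1 did not check the genotype labels. Sall2 and Sall3 did not pass the test either, with log2 differences of 0.18 (SE 0.17) and -0.27 (SE 0.28).

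Mutant and wild type kidneys differed most clearly at single genes. Cyp2e1, a cytochrome P450 of xenobiotic metabolism, rose from 3064 ± 692 (SD, n = 3) in wild types to 24022 ± 2853 (SD, n = 3) in mutants, a log2 change of 2.99 (SE 0.27). Kcnj1, the potassium channel ROMK of the thick ascending limb, fell from 50035 ± 3712 (SD, n = 3) to 21238 ± 1563 (SD, n = 3), a log2 change of -1.24 (SE 0.17). Cited1, a transcriptional co-regulator that marks the most undifferentiated nephron progenitors, fell from 28876 ± 11384 (SD, n = 3) to 8538 ± 1121 (SD, n = 3), a log2 change of -1.70 (SE 0.27). In all, 33 genes changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 23 higher and 10 lower in mutants. Unadjusted, 2196 genes had a limma p under 0.05, where 578.9 would be expected with no change and no structure shared by genes. That excess is not specific to genotype, since a split of the libraries by depth class gave 2903 such genes.

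Among the genes that rose, Kcne1l, an auxiliary potassium channel subunit, went from 4545 to 28938 (log2 change 2.70, SE 0.27) and Tenm2, a teneurin of the cell surface, from 3461 to 21626 (2.71, SE 0.31). Crabp1, a retinoic acid binding protein, rose by 1.88 (SE 0.22), Serpina6, the corticosteroid binding globulin, by 1.88 (SE 0.28), and Hsd11b1, which regenerates active glucocorticoid, by 1.86 (SE 0.31). Acox2, a peroxisomal oxidase of bile acid and branched fatty acid metabolism, rose by 1.92 (SE 0.34) and Abp1, a diamine oxidase, by 2.15 (SE 0.27). The organic anion transporters Slc22a30 (3.06, SE 0.43) and Slc22a28 (2.26, SE 0.37), Cml2 (1.99, SE 0.29) and Crisp1 (2.70, SE 0.41) also rose, but these belong to families of close paralogs and their values are uncertain where reads were shared.

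Among the genes that fell, Dkk1, a secreted Wnt antagonist, went from 25957 to 7347 (log2 change -1.85, SE 0.31) and Tmem100, listed with the progenitor genes, from 24477 to 5646 (-2.04, SE 0.34). Apom, an apolipoprotein made in kidney and liver, changed by -2.05 (SE 0.28), Afp, the fetal serum protein alpha-fetoprotein, by -1.79 (SE 0.27) and Shisa3 by -1.10 (SE 0.16). Defb1, a defensin of distal epithelia, changed by -1.27 (SE 0.20), or by -0.74 with the call lost (adjusted p = 0.278) once length and GC content were removed, and Ugt2b34, one of a family of similar glucuronosyltransferases, by -2.20 (SE 0.34). Smoc2, a matricellular protein of the stroma list, rose by 1.14 (SE 0.17). Adjusted p of the genes named as changed ran from 0.00150 for Cyp2e1 to 0.0433 for Acox2.

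**Figure D1:**
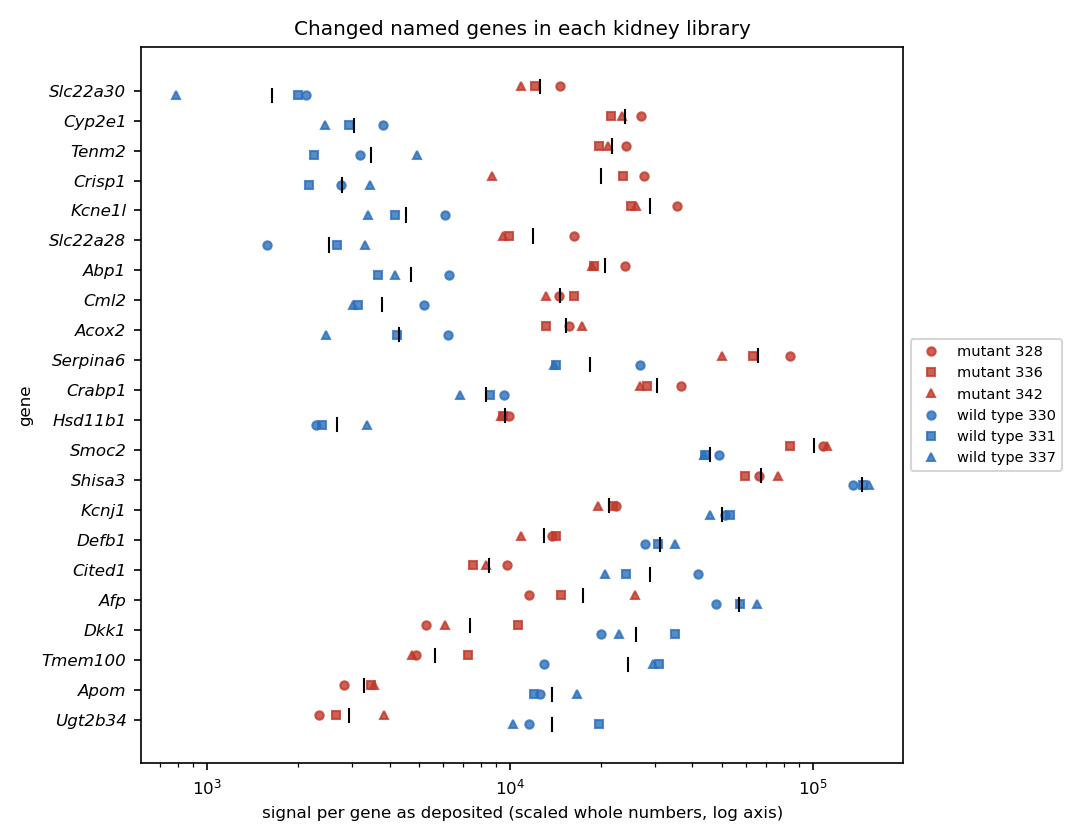
Signal of each changed gene named here, on a log axis, in the 3 mutant (red) and 3 wild type (blue) libraries, with black bars at the group means. For every gene shown the 3 mutant values lie on 1 side of the 3 wild type values, as for Cyp2e1 with mutants at 21508 to 27123 and wild types at 2446 to 3812.

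The loop of Henle list had 12 of its 15 genes in the table. Kcnj1 fell over all genes, and 5 members were lower adjusted over the list alone, namely Kcnj1, Slc12a1, Sostdc1, Irx2 and Pou3f3. Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, had a signal of 151490 in mutants and 277856 in wild types (log2 difference -0.86, SE 0.18, limma adjusted p = 0.0955 over all genes). Umod, uromodulin of the same segment, showed a log2 difference of 0.09 (SE 0.24). In limma 6 of the 12 had an unadjusted p under 0.05, and of these Irx1 (0.57, SE 0.26) was higher in mutants. The list as a set had a camera adjusted p of 0.0546, short of the threshold, and 0.55 with an estimated correlation. It passed with depth class as a covariate (adjusted p = 0.00583), a fit in which mutant 336 and wild type 330 weigh most. After removal of length and GC content it also passed (adjusted p = 0.00114). Leaving out 1 library, the camera adjusted p was 0.00639, 0.0722 and 0.109 without mutants 328, 336 and 342. It was 0.520, 0.00129 and 0.0292 without wild types 330, 331 and 337. With an estimated correlation these fits for depth class and for length and GC content gave 0.503 and 0.341. The median of the list, -0.23, was as unsteady, at -0.44 and -0.10 without mutants 328 and 336 and -0.13 and -0.36 without wild types 330 and 331, and it turned to 0.09 with array weights, where the test still pointed down (adjusted p = 0.577).

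Of the 15 nephron progenitor genes, Cited1 and Tmem100 fell over all genes and adjusted over the list alone, and 13 did not pass. In limma 7 had an unadjusted p under 0.05, and of these Uncx (0.84, SE 0.28) and Rspo1 (0.54, SE 0.19) were higher in mutants. Six2, the transcription factor that maintains progenitors, had a signal of 48428 ± 10498 (SD, n = 3) in mutants and 46452 ± 18355 (SD, n = 3) in wild types, a log2 difference of 0.11 (SE 0.27). The list's camera adjusted p was 0.0546, and 0.55 with an estimated correlation. It was 0.00583 with depth class as a covariate and 6.58e-04 after removal of length and GC content. Leaving out 1 library, it was 0.0240, 0.0722 and 0.0879 without mutants 328, 336 and 342. It was 0.461, 0.0183 and 0.0158 without wild types 330, 331 and 337. With an estimated correlation the fits for depth class and for length and GC content gave 0.503 and 0.147. The median was -0.21, and -0.14 without wild type 330 and -0.11 with array weights. In the early nephron list Dkk1 fell over all genes, and adjusted over the list alone Pax8 was higher (0.72, SE 0.20) and Dkk1 lower (camera adjusted p = 0.837). In the list of Wnt targets Dkk1 and Lgr5 (-1.52, SE 0.33) were lower adjusted over the list alone (camera adjusted p = 0.569).

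The proximal tubule list was higher in mutants as a set, with a median log2 difference of 0.48 over its 20 genes (camera adjusted p = 8.36e-05). That call was lost when the correlation between genes was estimated (adjusted p = 0.55 with an estimated correlation), and the list did not pass by fry (adjusted p = 0.193). The median was 0.31 without mutant 328, 0.32 without wild type 337 and 0.75 without mutant 336. It was 0.31 with depth class as a covariate, 0.29 after removal of length and GC content, 0.21 with both and 0.76 with array weights. In limma 0 of 20 passed over all genes, with 8 at an unadjusted p under 0.05, and 7 were higher adjusted over the list alone, among them Kap (1.50, SE 0.28), the gluconeogenic enzymes Pck1 (1.38, SE 0.29) and Fbp1 (0.88, SE 0.23), and the glucose transporter Slc5a2 (1.27, SE 0.30). Lrp2, megalin, the list's most abundant member, showed -0.12 (SE 0.19).

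The macrophage and leukocyte list was also higher, with a median of 0.61 over 9 genes (camera adjusted p = 3.83e-04, fry adjusted p = 9.04e-04, adjusted p = 0.267 with an estimated correlation). In limma 0 of 9 passed over all genes, with 6 at an unadjusted p under 0.05, and 5 were higher adjusted over the list alone, led by C1qc (1.64, SE 0.34), a complement subunit made by tissue macrophages, and Csf1r (0.95, SE 0.21), their growth factor receptor. Within a depth class either list could be compared only with 1 library on one side, mutant 336 in the lower class and wild type 330 in the higher. Tests within classes are therefore not used as evidence for these lists. The stroma list moved in 1 direction by fry (adjusted p = 0.0213) but not against other genes by camera (adjusted p = 0.199). Smoc2 rose over all genes, and over the list alone Smoc2 and Foxd1 (0.75, SE 0.22) were higher and Rarb lower (-0.69, SE 0.22).

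Of the distal tubule list, Trpv5 was higher and Tmem52b and Slc8a1 were lower adjusted over the list alone, and 0 passed over all genes in limma, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.134, or 0.0419 in the lower direction after removal of length and GC content, where an estimated correlation gave 0.366). In the collecting duct list Atp6v1g3 was lower adjusted over the list alone (-1.18, SE 0.32), and the list as a set had a camera adjusted p of 0.990. Cdkn1a (0.94, SE 0.19) and Phlda3 (1.04, SE 0.23), both p53 targets, were higher over the list alone, as were Jun and Junb among handling genes (camera adjusted p = 0.524 and 0.0546), with 0 of either list past the threshold over all genes in limma and 4 and 3 at an unadjusted p under 0.05. The proliferation and sex-linked lists each had a camera adjusted p of 0.0546 with 0 members past the threshold in limma and 5 of 20 and 1 of 4 at an unadjusted p under 0.05, Mki67 at -0.69 (SE 0.20) and Ddx3y at -0.33 (SE 0.22). Among all 11578 genes 2196 had such an unadjusted p in limma, the share to set beside each of these list counts. The podocyte, ureteric tip, endothelium, erythroid, Notch, NuRD, Sall and injury lists, in that order, had 0 members past the threshold in limma by either count, 1, 2, 5, 0, 2, 2, 0 and 1 at an unadjusted p under 0.05, and camera adjusted p of 0.296, 0.593, 0.134, 0.837, 0.569, 0.906, 0.736 and 0.524. After removal of length and GC content the ureteric tip list passed in the lower direction with the preset correlation (adjusted p = 0.0142, median -0.36 against -0.02), but not with an estimated one (adjusted p = 0.341). No adrenal gene of 10 and 1 muscle gene of 8, Actn3 (-0.49, SE 0.34), was in the table, so these lists were not tested.

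**Figure D2:**
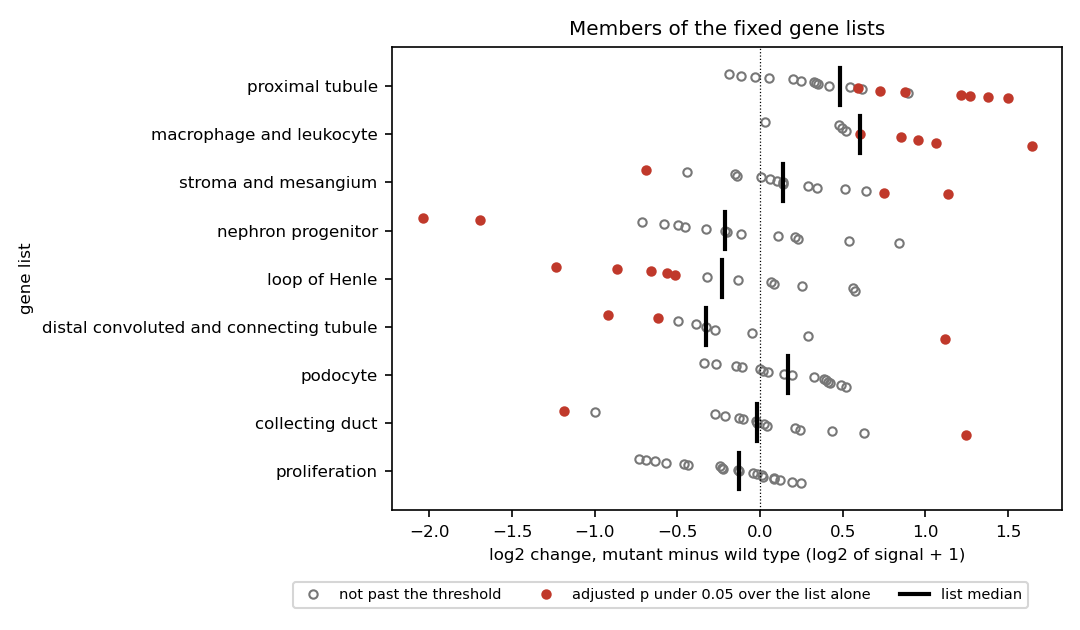
Log2 change of each listed gene, mutant minus wild type, for 9 of the fixed gene lists, with filled points for members past the threshold adjusted over the list alone and black bars at list medians. The proximal tubule median lies at 0.48 and the loop of Henle median at -0.23 with all 6 libraries weighted alike, with members of each list on both sides of 0.

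The libraries did not divide by genotype alone. Component 1 held 60.0% of the variance and set wild types 331 and 337 apart from the other 4 libraries, and wild type 330 correlated across genes at 0.975 and 0.980 with mutants 328 and 342 but at 0.924 and 0.914 with wild types 331 and 337. Genes are not independent replicates, so no p is given for these values. The number of changed genes depended on every library, being 2, 12 and 5 without mutants 328, 336 and 342, and 3095, 3 and 17 without wild types 330, 331 and 337. It was 43 with the depth class as a covariate. The 33 genes kept their direction in each of these fits, which could not turn it, since their mutant and wild type values do not overlap. Cyp2e1 and Kcne1l passed in all 22 alternative limma fits, whereas 0 genes passed when the authors' p-values were adjusted.

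**Figure D3:**
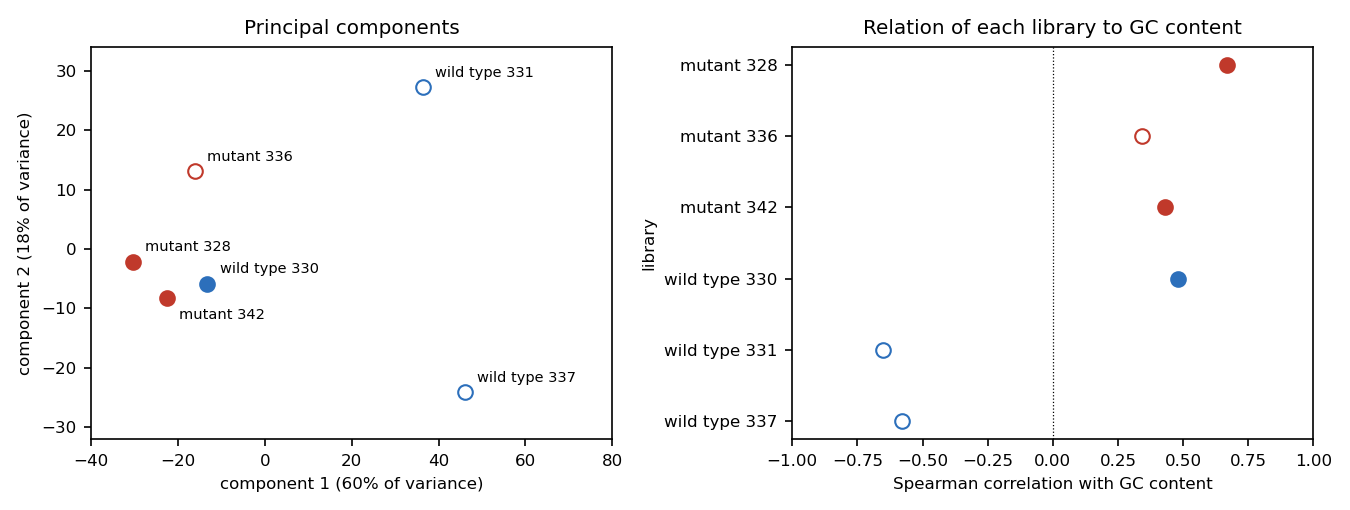
Left, the first components of the log2 values, and right, the Spearman correlation across genes between GC content and each library's deviation from the gene mean, for mutants (red) and wild types (blue), filled for higher and open for lower depth. The correlation is 0.48 in wild type 330 and 0.34 to 0.67 in the mutants, against -0.65 and -0.58 in wild types 331 and 337.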

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

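The fits by depth class, length and GC content, array weights, the minimum mean of 10000, the pseudocount of 1000 and the authors' test were chosen after the data were seen. All 33 changed genes that a fit held kept their direction in every alternative limma fit. For most fits that was fixed in advance, since the mutant values of each gene all lie on 1 side of its wild type values. Leaving out, weighting or grouping libraries then cannot turn a direction. Only quantile normalization, rescaling and removal of length and GC content could have done so. Leaving out 1 library moved the number of changed genes between 2 and 3095, of higher genes between 2 and 1670, of lower genes between 0 and 1425, of lists past the threshold between 3 and 5, and the Sall1 log2 difference between -0.27 and -0.12. The extremes of the gene counts were without mutant 328 and without wild type 330. Of 33 changed, 23 higher and 10 lower genes and 2 lists, other settings gave 16 lower with quantile normalization, where 61.9% of 42 calls were higher against 69.7%, 15 higher without the trend, and 16 lower at an adjusted p under 0.1. Each depth class alone has 1 library of one genotype, which is assumed to vary like the others, so these values are no separate evidence. The libraries with steps below 1 alone, with wild type 330 as the lone wild type, gave 70 changed, 56 higher and 12 lists, and those with steps above 1 alone, with mutant 336 as the lone mutant, 699 changed, 305 higher, 394 lower and 0 lists, with 43.6% higher. Array weights gave 3493 changed, 1915 higher and 1578 lower, with a weight of 0.298 for wild type 330 and 5.33 for mutant 328. Removal of length and GC content gave 18 lower genes and 7 lists, and 7 lists with depth class added, in both fits the proximal tubule, macrophage, progenitor, loop of Henle, proliferation, distal tubule and ureteric tip lists. Depth class as a covariate gave 5 lists, adding progenitor, loop of Henle and proliferation, the minimum mean of 10000 also 5, and camera with an estimated correlation 0, as it did with depth class as a covariate, after removal of length and GC content, and with both. The authors' test with Benjamini-Hochberg adjustment gave 0 genes, against 1009 at an unadjusted p under 0.05. Fewer libraries are tested in part of these fits, and otherwise the cause was not tested. Filters at 1 and 5 removed no gene and so tested nothing.

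Direction turned for some named genes and for 9 of 21 lists that had not passed. After removal of length and GC content, without and with depth class, log2 differences were -0.12 and -0.0896 for Cdkn1c, -0.0566 and -0.0973 for Notch1, 0.21 and 0.19 for Ddx3y, -0.11 and -0.15 for Fn1, and -0.10 and -0.0606 for Cdh5. Sall2 was at -0.0422 with that removal, and Hba-a1 at -0.0653 with depth class added. In libraries with steps below 1 alone they were 0.0645 for Ddx3y, -0.0969 for Hba-a1 and -0.0817 for Fn1. Hba-a1 was at -0.0109 with depth class as a covariate, and between -0.0145 without mutant 342 and 0.62 without wild type 330. Lrp2 was between -0.30 without mutant 328 and 0.0205 without mutant 336, and at 0.13 with array weights, where Sall3 was at 0.0543. Of 34 list values that turned, 1 passed the threshold, the collecting duct list at an adjusted p of 5.05e-04 in the lower direction with steps below 1 alone, against wild type 330 as the lone wild type. The other adjusted p in the turned direction were as follows. After removal of length and GC content they were 0.796 for podocyte, 0.279 for collecting duct, 0.916 for erythroid, 0.147 for Notch, 0.569 for NuRD and 0.974 for sex-linked. With depth class added they were 0.486 for collecting duct, 0.777 for erythroid and for sex-linked, 0.0597 for Notch and 0.413 for NuRD. With steps below 1 alone they were 0.799 for erythroid, 0.224 for Notch and 0.432 for NuRD, and with steps above 1 alone 0.568 for early nephron and for ureteric tip, 0.623 for erythroid and 0.663 for Sall. Array weights gave 0.986 for early nephron and erythroid, depth class as a covariate 0.871 for erythroid, and no trend 0.929 for collecting duct. Leaving out 1 library, some of these fits turned as well, and the adjusted p ran from 0.561 to 0.984 for early nephron, 0.294 to 0.984 for ureteric tip, 0.487 to 0.994 for collecting duct, 0.399 to 0.979 for erythroid, 0.653 to 0.984 for NuRD and 0.407 to 0.984 for Sall. The cause was not tested. Named genes lost a call in 105 alternative values and gained one in 16, and lists, with camera's preset correlation, in 2 and 37. Outside that count, the proximal tubule and macrophage lists lost their call with an estimated correlation, and the proximal tubule list by fry. The macrophage list's estimated correlation was -0.0904, below the preset 0.01, so a higher correlation does not account for its loss. Depth per gene cannot be given, since the unit of the steps is unknown.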

Other observations

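The tests of chance, linkage, the scan of symbol families, the midpoint counts, the depth class covariate on the proximal tubule list, the common factor of its members and the correlation gap after length and GC removal were chosen after the results were seen. Meg3, a maternally expressed long noncoding RNA of the imprinted Dlk1 region on chromosome 12, rose from 20095 to 59791 (log2 change 1.62, SE 0.24, limma adjusted p = 0.0201). It was singled out after its value was seen. Its neighbour Rian had a log2 difference of 0.74 (SE 0.21, adjusted p = 0.231) and Dlk1 of 1.94 (SE 0.68, adjusted p = 0.233), neither past the threshold. Among 174 families of genes sharing a symbol stem, the 35 collagen genes were higher as a set (camera adjusted p = 0.0104), with 28 of 35 positive and a median log2 difference of 0.36. That call was lost with an estimated correlation (adjusted p = 0.943) and after removal of length and GC content (adjusted p = 0.845), where the test still pointed up. In that last fit the Cyp family passed instead, in the higher direction (camera adjusted p = 0.0223). With depth class as a covariate the collagen genes passed (camera adjusted p = 1.31e-04). So did the families Rpl, Rps, Eif and Mrpl (2.00e-05, 1.24e-04, 0.0434 and 0.0434). Without that covariate these families pointed lower in mutants, with median log2 differences of -0.14, -0.14, -0.19 and -0.10. They did not pass there (camera adjusted p = 0.331, 0.156, 0.136 and 0.434).

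The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The labelled split gave 33 changed genes and the highest other split 1, so 1 split of 10 gave as many. The split that follows the depth classes had 2903 genes at an unadjusted p under 0.05 against 2196 for the genotypes, and 889 against 49 at an adjusted p under 0.1, which points to a structure of the samples. With depth class as a covariate 43 genes changed. Genes near Sall1 showed no excess of change, with 7 of 289 genes within 20 Mb at an unadjusted p under 0.01, 12.3 expected and 0 called. The odds ratio was 0.55 (0.218 to 1.16, Fisher p = 0.139). This argues against a broad effect of linkage to the mutated allele, but cannot exclude an effect on a few genes.

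Wild type 330 lay nearer to the mutants than to the other wild types. Removing gene length and GC content took the genes changed without wild type 330 from 3095 to 615. That count leaves this library out and so does not place it. The lowest correlation of wild type 330 with mutants 328 and 342 exceeded its highest with wild types 331 and 337 by 0.0511 before the removal. After it the gap was 0.0226 (0.0195 to 0.0254 over resampled genes), so length and GC content may account for part of the nearness. Whether they account for all of it cannot be told, since the splines may remove them only in part. Depth class cannot be told apart from these, as the lower-minus-higher depth difference correlated across genes at 0.365 between mutants and wild types, between the bounds set for it. A mislabelled sample cannot be told apart either. Positions were taken along the 100 top genes between mutant 336 and wild types 331 and 337. Wild type 330 lay 0.151 of the way further towards the wild types than the mean of mutants 328 and 342. The interval over resampled genes, 0.0856 to 0.218, holds the bound of 0.2 but does not hold the spread between libraries. The positions were 0.185 and 0.352 for mutants 328 and 342 and 0.419 for wild type 330. A further count tried after that result also left it open, because its answer changed with the minimum change: of genes changed without wild type 330, it lay past the midpoint towards the wild types at 8.79% with no minimum, against 22.7% for mutant 336 held out likewise, but at 47.6% against 14.6% for genes changed at least 4-fold, and 5 minimums were tried.

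The proximal tubule list was higher in mutants with the preset correlation, and not with an estimated one (adjusted p = 0.55). With the preset correlation the camera adjusted p was 2.35e-04 with depth class as a covariate and 3.99e-05 after removal of length and GC content. Leaving out 1 library it ran from 1.45e-08 to 0.00175, the latter without wild type 330. With an estimated correlation the fits for depth class, for length and GC content and for both gave 0.503, 0.341 and 0.439. The list passed in none of these, so they cannot argue against depth class or length and GC content as the whole cause. The median of 0.48 was 0.31 with depth class, 0.29 after length and GC removal and 0.21 with both. Leaving out 1 library moved it about as far, to 0.31 without mutant 328, 0.32 without wild type 337 and 0.75 without mutant 336. No test compared these medians, so whether part of the difference goes with depth class or length and GC content is open. A larger share of proximal tubule cells would raise all members by a common factor only if each were expressed in these cells alone and evenly across them. The members' log2 differences ran from -0.19 to 1.50 and scattered around a common 0.46. Their heterogeneity Q was 72.0 against 19 degrees of freedom (p = 0.0120 by an F approximation to limma's moderated errors, not an exact test). Even expression was not tested, so the scatter argues against a common factor but not against a larger share. No test here separates a change within proximal tubule cells from a larger share combined with other differences, and both stay open.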
